A study of Eumeta variegata with 6 samples.

How the data were processed

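The series holds RNA sequencing of heads of Eumeta variegata, 3 male and 3 female libraries, grouped by the sex in the labels. Per the labels' protocols, total RNA was extracted with Trizol and made into stranded mRNA libraries. The submitters' processing notes name Trimmomatic, HTSeq and R 3.2.0 without saying what each was used for. The aligner, the assembler's version and any filter are not given in the sources used here. The deposited table gives FPKM (fragment counts scaled by sequence length and library total), as calculated by the authors, for each assembled sequence in each library, with the authors' protein and pathway annotation beside it. Sequence names have the form written by the Trinity assembler. FPKM values divide by sequence length and library total, so they hide the number of reads behind each value. Ratios of low values between libraries showed no whole-read steps: the most common window of 0.02 log2 units held at most 1.94% of them. Depth is therefore unknown, no counting interval can be given, and tests for counts were not used. No reference genome was used here, so sequences have no coordinates.

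A sequence took its name from the NR description, or from Swiss-Prot where NR gave none that was informative. NR named 10737 sequences and Swiss-Prot 2154. This order was chosen after the columns were seen and before any values were compared. Names come from similarity to other species and say nothing certain about function in this moth. Several sequences can stand for 1 gene, and near-identical copies may share reads, so values of single family members are uncertain.

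Values were turned into log2(FPKM + 1). Sequences with an FPKM of at least 1 in at least 3 of the 6 libraries were kept, which left 35198. A fold change on this scale is the mean of males minus the mean of females, and it understates the change of low sequences. The sexes were compared with limma 3.58.1 in R 4.3.3, using its moderated test with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment over all kept sequences and a threshold of 0.05. No replicate block and no minimum fold were used. The test, the filter, the 24 gene lists, the rule for named sequences and most alternatives were fixed before the data were examined.

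Gene lists were matched on the description text. They were neuropeptide precursors, receptors and processing enzymes; amine and transmitter receptors; odorant-binding proteins; odorant, gustatory and ionotropic receptors; phototransduction; circadian clock; synapse; muscle; oxidative phosphorylation; ribosome; cuticle; fat body; egg, ovary and testis; silk and salivary gland; gut; immunity; pheromone and fatty acid synthesis; juvenile hormone and ecdysteroid; detoxification; sex determination; heat shock; transposon and virus. Matching on words takes in some proteins of other kinds. Each list was counted among the calls over all sequences and adjusted over the list alone, and tested with limma's camera at a preset correlation of 0.01 and at an estimated correlation, with Benjamini-Hochberg adjustment over the 24 lists. The rule named the 8 annotated sequences with the largest change in each direction with an adjusted p below 0.05, a mean FPKM of at least 10 and no overlap of the sexes, 1 per description. It also named up to 5 called members in each direction of the neuropeptide precursor and receptor lists, up to 2 in each other list, and the most abundant member of a list with no call.

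Shares of the most abundant sequences were compared by an exact permutation test. The split of the libraries by the ending of the sequence names was found in the data. It was then used as a model term, an alternative chosen after seeing the data, as were lists without misleading matches, lists from NR names alone, and fits to each name ending alone. Other alternatives were pseudocounts of 0.1 and 0.5, other filters, rescaling to a common sum, median-of-ratios and quantile scaling, robust shrinkage, array weights, a replicate block, each library left out, and a minimum log2 fold change of 1.

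The fit was tested on simulated data: values were drawn for the 35198 sequences from their means and residual spread, with 200 changed. Each value was drawn independently, and the changed sequences were taken only from those with a mean log2(FPKM + 1) above 2. Recovery of lower sequences was not tested. Of the sequences changed by a log2 fold of 1, 59% were recovered, and of those changed by 2, 87%, with 6 false calls among 152. With nothing changed there were 0 calls.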

Results

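Gene expression was measured by RNA sequencing in heads of the bagworm moth Eumeta variegata, in 3 male and 3 female libraries. Bagworms are moths whose caterpillars live in a portable silk case, and the adult sexes look very different: males are winged and fly, whereas females are wingless. The labels place the work in a search for neuropeptides, the peptide hormones and transmitters of the nervous system, and for their receptors. They give the sex and the tissue of each sample but not the age or stage, and they do not say whether the samples of a sex came from separate animals or pools. The p-values below therefore measure only the spread between these samples, which may be technical. The table held 41283 assembled sequences with an FPKM value in each library, of which 12891 carried a usable protein name. Depth was unknown, because FPKM values carry no read totals. Library sums lay between 480295 and 492028 FPKM, and 30100 to 32360 sequences reached an FPKM of 1 per library. Pearson correlations of log2 values, taken across sequences, which are not independent replicates, were 0.85 to 0.89 between males, 0.86 to 0.88 between females and 0.80 to 0.86 between the sexes. The first principal component held 33.5% of the variance, with the 3 males on one side and the 3 females on the other.

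The question of the main comparison was which transcripts differ between male and female heads. Among named sequences with a mean FPKM of at least 10, cuticle proteins, which form the insect's outer skeleton with chitin, led those that were higher in males. Cuticle protein 1 (TRINITY_DN2639_c0_g1_i1_1) had 568 ± 101.1 FPKM in males and 2.05 ± 0.60 in females (mean ± SD, n = 3 each), a log2 fold change of 7.55 (SE 0.18, limma adjusted p = 9.1e-05). Pupal cuticle protein PCP52 (log2 fold change 4.47), a sequence named Cuticle protein (4.36), Larval cuticle protein LCP-17 (4.25) and a sequence named Pupal cuticle protein (3.84) followed. The other 3 named sequences at the top in males were Zinc finger protein Gfi-1 (2.33), Protein PELPK1 (2.12) and an alpha-tocopherol transfer protein-like sequence (2.10). Among such sequences the largest difference in females was in Arylphorin subunit alpha (TRINITY_DN18247_c0_g1_i1_1), a hemolymph storage protein made by the fat body. It had 0.072 ± 0.031 FPKM in males and 27.0 ± 1.7 in females, a log2 fold change of -4.71 (SE 0.11, limma adjusted p = 9.1e-05). Fungal protease inhibitor-1 came next, with 21.6 ± 11.7 FPKM in males and 286 ± 59 in females (log2 fold change -3.83, SE 0.46). Zonadhesin 4-like (-3.61), Apolipophorin-3, a lipid carrier of the hemolymph (-3.28), Ommochrome-binding protein (-3.0), Gamma-glutamylcyclotransferase (-2.53), Protein lethal(2)essential for life, a small heat shock protein (-2.51), and Acidic juvenile hormone-suppressible protein 1 (-2.48) completed the list. No overlap between the sexes' values was a condition for naming these 16 sequences. The call of Acidic juvenile hormone-suppressible protein 1 ended without male 1 (its limma adjusted p over the alternatives reached 0.053).

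**Figure D1:**
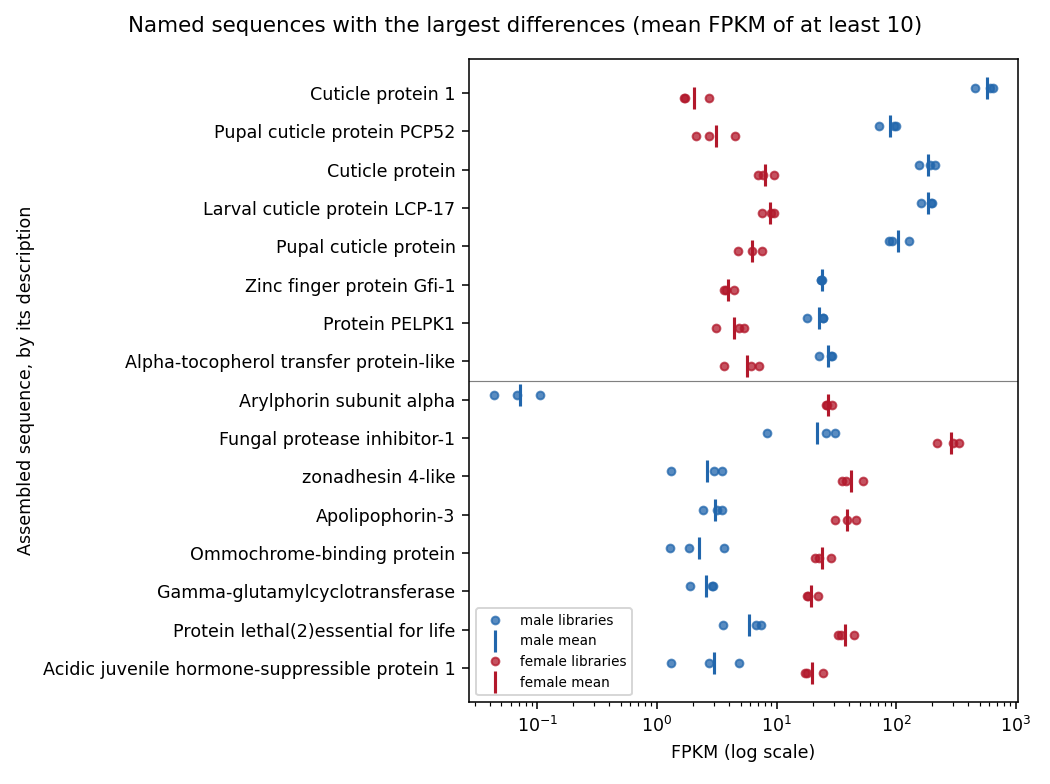
FPKM on a log scale of the 16 named sequences with the largest log2 fold changes among those with a mean FPKM of at least 10 and no overlap between the sexes, 8 higher in males (above the line) and 8 higher in females (below it); dots are libraries and vertical ticks are the means of 3. Cuticle protein 1 has a mean of 568 FPKM in males and 2.05 in females, and Arylphorin subunit alpha 0.072 in males and 27.0 in females.

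In all, 2501 of the 35198 sequences tested differed at a limma adjusted p below 0.05, 1549 of them higher in males and 952 higher in females. Among these, 672 male and 359 female calls had a log2 fold change of at least 1. The values of the sexes did not overlap in 30.2% of the sequences tested, where chance gives 10% for 3 against 3. The excess of male calls, 61.9%, became 51.4% when libraries were scaled by the median of ratios (1329 higher in males, 1258 in females). Leaving out 1 library lowered the count to 822 without male 1, 837 without male 2, 910 without male 3, 1107 without female 2 and 1326 without female 3.

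The libraries also split in a way that was not the sex. Sequence names ended in 1 (22120 sequences) or in 2 (19163 sequences). Male 2, male 3 and female 2 listed fewer sequences at 0 among names ending in 1, and male 1, female 1 and female 3 listed fewer among names ending in 2. In male 3, for example, 2.96% of the first kind and 9.98% of the second were listed at 0, against 13.2% and 4.32% in female 1. Of the changed sequences with ending 1, 74.0% were higher in males (1054 against 370), and of those with ending 2, 46.0% were (495 against 582). With this split as a term in the model, 1136 sequences differed, 712 higher in males and 424 in females. The 1410 calls that ended had a median absolute log2 fold change of 0.69 both without and with the term, with a median SE of 0.13 without it and 0.15 with it, and the residual degrees of freedom went from 4 to 3. Fold changes without and with the term correlated at 0.96 across all sequences tested, which are not independent replicates. For the 19 named sequences whose call ended, the log2 fold change moved by at most 0.12. Each set holds a single library of one sex, so no test was made within a set.

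**Figure D2:**
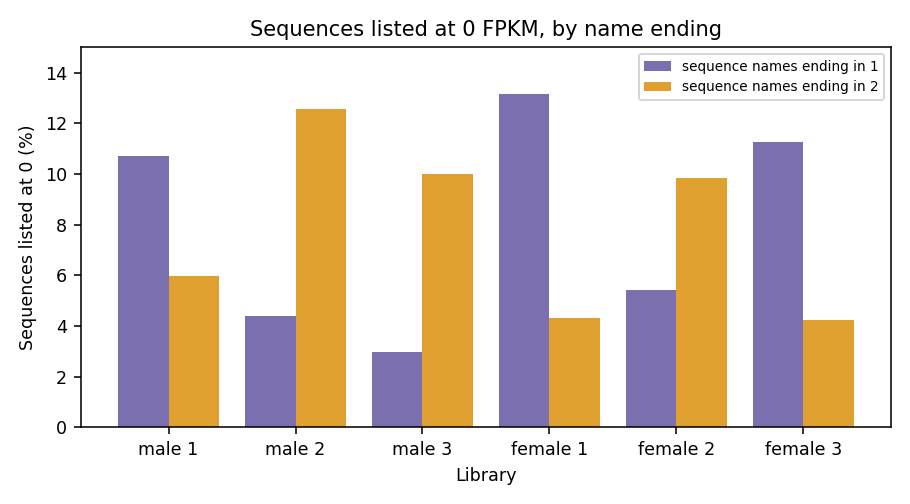
Percent of sequences listed at 0 FPKM in each library, for sequence names ending in 1 and in 2. Male 2, male 3 and female 2 have the shorter bar for ending 1 (2.96% to 5.42%), and male 1, female 1 and female 3 the shorter bar for ending 2 (4.25% to 5.96%).

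Among the neuropeptide precursors and receptors tested, 3 sequences were called. That share is near the 7.1% of all sequences tested that changed, so it does not set these lists apart. Of the 22 precursors tested, 1 was higher in males and none in females. It was Pro-neuropeptide Y (TRINITY_DN9754_c1_g1_i1_2), of a peptide family linked to feeding, with 3.59 ± 0.10 FPKM in males and 0.61 ± 0.16 in females (log2 fold change 1.52, SE 0.20, limma adjusted p = 0.011). Its call ended without male 1, male 2 or male 3. The list's median log2 fold change was 0.62 and 20 of its 22 members lay above 0. The gene set test camera gave an adjusted p of 0.0027 with a preset correlation and an adjusted p = 0.78 with an estimated correlation. The 22 members varied together among the libraries: their median distance from each member's mean was -0.59 in female 1, -0.50 in female 2 and 0.11 in female 3, against 0.23, 0.44 and 0.28 in males 1, 2 and 3. Their median log2 fold change was 0.83 within males 2 and 3 against female 2, and 0.45 within male 1 against females 1 and 3. Of the 24 receptor sequences, the Neuropeptides capa receptor was higher in males (5.71 ± 0.38 against 1.69 ± 0.74 FPKM, log2 fold change 1.35, limma adjusted p = 0.023), and Insulin-like growth factor 1 receptor was higher in females (6.07 ± 0.52 against 9.12 ± 1.03 FPKM, -0.52, limma adjusted p = 0.044). The capa receptor call ended without any one of the males or without female 1. The insulin-like growth factor receptor call ended without any one of the 6 libraries, and with the library split in the model (adjusted p = 0.11, over all alternatives 0.016 to 0.13). Adjusted over the list alone, 1 precursor was higher in males, and 1 receptor was higher in males and 3 in females. Over both lists the 3 calls became 5 with median-of-ratios scaling (2 higher in males, 3 in females). They became 1 without male 1 or female 1, and 0 without male 2 or male 3. At an unadjusted limma p below 0.05 were 6 of the 22 precursors and 8 of the 24 receptors, beside 8214 of all 35198 sequences tested. No call was made for 21 precursors and 22 receptors. Of 11 enzymes that process neuropeptides, Carboxypeptidase E alone was called (27.9 ± 1.3 against 20.5 ± 0.6 FPKM, log2 fold change 0.43, higher in males).

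Of 73 cuticle proteins tested, 39 were higher in males and none in females, with a median log2 fold change of 1.07. Adjusted over the list alone, 48 were higher in males and 1 in females. The camera test gave an adjusted p of 1.0e-22 with a preset correlation, and it was the only one of 24 lists to keep a call with an estimated correlation (adjusted p = 0.0060). The median was 1.04 within males 2 and 3 against female 2, and 1.01 within male 1 against females 1 and 3. With the library split in the model 26 were higher in males. The count was 23 without male 1 or male 2, and 25 without female 2. The list was matched on names and also takes in enzymes that make or cut chitin.

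**Figure D3:**
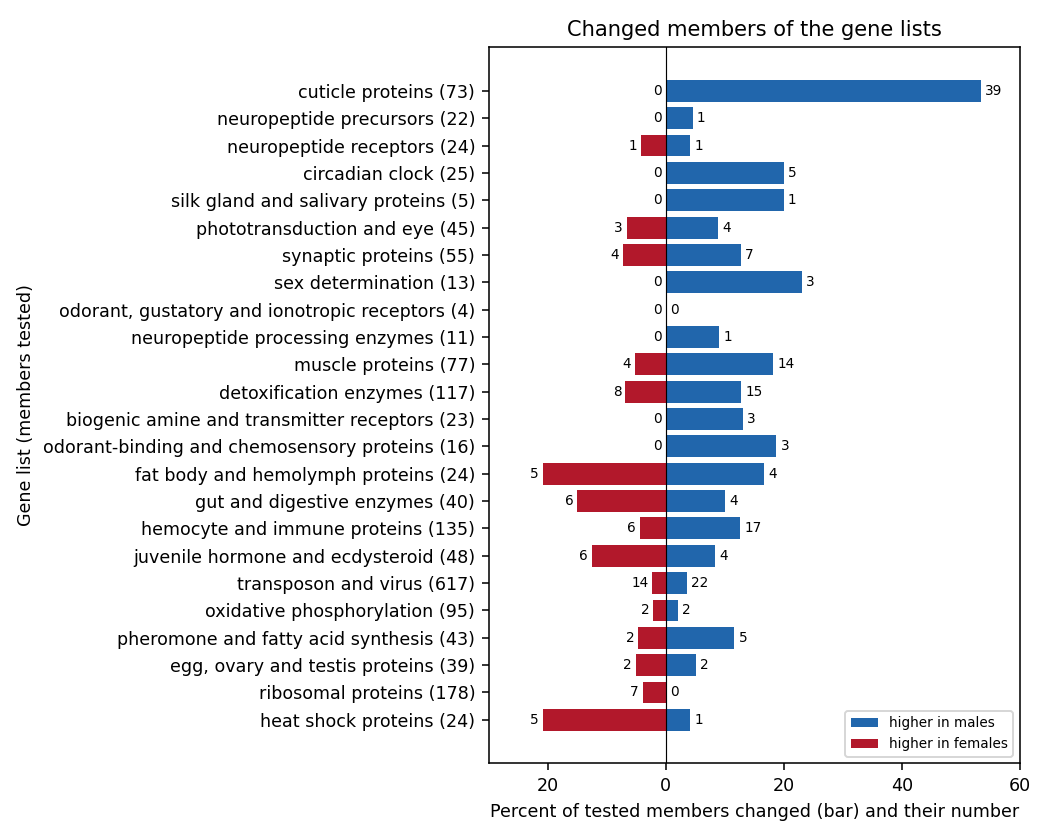
Percent of tested members of each of 24 gene lists that were higher in males (right) or in females (left), with their numbers at the bars and the members tested in brackets. Of the cuticle proteins, 39 of 73 were higher in males and 0 in females.

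Over all lists other than the neuropeptide precursors and receptors, 230 members were called, and 125 with the library split in the model. Without male 1, male 2 or male 3 these were 97, 103 and 113, and without female 2 or female 3 they were 120 and 146. Fat body and hemolymph proteins went both ways, with 4 of 24 higher in males and 5 in females (6 each adjusted over the list alone). With median-of-ratios scaling these were 2 and 5, and with the library split 0 and 3. Besides Arylphorin subunit alpha and Apolipophorin-3, described above, 27 kDa hemolymph protein (log2 fold change 1.43) and a Transferrin, an iron carrier (0.78), were higher in males. The Transferrin call ended without any one of the 6 libraries and that of 27 kDa hemolymph protein without any one of the males, and both ended with the library split. Sequences with the juvenile hormone and ecdysteroid names, which cover the hormones of moulting and maturation, were higher in males for 4 of 48 and in females for 6 (10 and 8 adjusted over the list alone, and 3 each with the library split). Juvenile hormone-binding protein, a carrier of the hormone, had 0.94 ± 0.30 FPKM in males and 17.3 ± 4.1 in females (log2 fold change -3.22). Farnesol dehydrogenase (1.32) and ecdysone-induced protein 74EF isoform X1 (0.77), a transcription factor, were higher in males. The call of Farnesol dehydrogenase ended without any one of the males. Heat shock proteins were higher in females for 5 of 24 and in males for 1, and adjusted over the list alone for 9 and 3. With the library split these were 2 and 1. Heat shock protein homolog (-1.34) and Heat shock factor protein (-0.63) were higher in females, and Heat shock protein beta-1 (0.57) in males, a call that ended without any one of the males. The camera adjusted p of this list was 0.020 with a preset correlation, and the adjusted p = 0.46 with an estimated correlation. Before adjustment the camera p was 0.0033 and 0.038. The estimated correlation was 0.0064, below the preset 0.01, so a higher correlation does not explain the larger p. The 2 versions of camera therefore differ in more than the correlation, here and for the other lists. Immune and hemocyte proteins were higher in males for 17 of 135 and in females for 6 (26 and 13 adjusted over the list alone, and 8 and 2 with the library split). Alaserpin (1.99) and Lysozyme c-1 (1.69), an enzyme that cuts bacterial walls, were higher in males, and Attacin-E, an antibacterial peptide (-1.21), and a tolloid-like protein (-1.45) in females. The Attacin-E and tolloid-like calls ended without any one of the 6 libraries and with the library split, and that of Alaserpin without any one of the males. The tolloid-like sequence is a protease matched by the word toll and is not an immune gene by its name.

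Among sensory and neural lists, odorant-binding and chemosensory proteins were higher in males for 3 of 16 and in females for none (4 and 0 adjusted over the list alone). Putative odorant-binding protein A10 had 32.2 ± 1.3 FPKM in males and 13.6 ± 2.6 in females (log2 fold change 1.20), and General odorant-binding protein 19d had a log2 fold change of 1.59, a call that ended without any one of the males. None of the 4 odorant, gustatory and ionotropic receptors tested passed the limma test, and 0 had an unadjusted p below 0.05. The most abundant, putative ionotropic receptor IR25a, had 2.67 ± 0.25 FPKM in males and 2.31 ± 0.20 in females. The circadian clock list was higher in males for 5 of 25 (8 and 1 in females adjusted over the list alone). Its leading members, Circadian clock-controlled protein (1.84) and Protein takeout (1.73), belong to a family of secreted ligand-binding proteins and are not parts of the clock itself. The call of Protein takeout ended without male 1 or male 2. Its camera adjusted p was 0.027, and the adjusted p = 0.66 with an estimated correlation. Phototransduction and eye sequences were higher in males for 4 of 45 and in females for 3, the same numbers as adjusted over the list alone. With the library split these were 2 and 1. Retinol dehydrogenase 11 (1.18) and Arrestin domain-containing protein 1 (0.99) were higher in males, and Ommochrome-binding protein and Lambda-crystallin homolog (-0.56) in females. These were matched by words, and their names alone do not place them in the eye. The arrestin domain match was among those treated as misleading. With the library split all of these sequences but Ommochrome-binding protein lost their call, at log2 fold changes of 1.21, 0.91 and -0.57. So did the first pair without any one of the 6 libraries, and Lambda-crystallin homolog without any one of the males or female 2. Biogenic amine and transmitter receptors were higher in males for 3 of 23, also adjusted over the list alone, and for 1 with the library split. They included glutamate receptor ionotropic, NMDA 2B (0.94) and a 5-hydroxytryptamine receptor (0.76). Both calls ended with the library split, the former without any one of the 6 libraries and the latter without any one but female 3. Synaptic proteins were higher in males for 7 of 55 and in females for 4 (10 and 5 adjusted over the list alone, and 4 and 1 with the library split), with a camera adjusted p of 0.032 and an adjusted p = 0.62 with an estimated correlation. One Synaptic vesicle glycoprotein 2B sequence rose to a log2 fold change of 1.82 in males, and another had -0.86. Neuroligin-4, Y-linked (0.69) was higher in males and Syntaxin-16 (-0.49) in females. The word Y-linked belongs to a name from another species and says nothing about a chromosome here. The Syntaxin-16 call ended with the library split and without any one of the 6 libraries, and that of the second glycoprotein 2B sequence without male 2, male 3 or female 2.

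Muscle proteins were higher in males for 14 of 77 and in females for 4 (20 and 8 adjusted over the list alone, and 11 and 2 with the library split). Paramyosin, short form, of the thick filament, had 8.31 ± 1.45 FPKM in males and 1.39 ± 0.71 in females (log2 fold change 1.99). The flightin isoform X1 sequence, of the flight muscle, had 32.6 ± 5.4 in males and 85.9 ± 17.0 in females (-1.36). The list also matched Unconventional myosin-VIIb (1.18) and unconventional myosin-XVIIIa isoform X1 (-0.88), motor proteins of other cells. The paramyosin call ended without male 1 or male 2, and that of Unconventional myosin-VIIb without any one of the males. Ribosomal proteins were higher in females for 7 of 178 and in males for none (5 and 0 adjusted over the list alone, and 2 and 0 with the library split), with a median log2 fold change of -0.13. Their camera adjusted p was 1.2e-05, and the adjusted p = 0.62 with an estimated correlation. 60S ribosomal protein L15 (-0.69) and 60S ribosomal protein L39 (-0.59) led. Oxidative phosphorylation had 2 of 95 higher in males and 2 in females (0 and 2 adjusted over the list alone). With median-of-ratios scaling these were 0 and 3, and with the library split 0 and 1. They were ATP synthase subunit beta (0.27) and NADH dehydrogenase 1 alpha subcomplex subunit 13 (0.26) in males, and Cytochrome c oxidase subunit 7C (-0.64) and ATP synthase subunit delta (-0.34) in females. All but Cytochrome c oxidase subunit 7C lost their call with the library split. ATP synthase subunit beta and the NADH dehydrogenase subunit also lost it without any one of the 6 libraries, and ATP synthase subunit delta without any one but female 1.

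Detoxification enzymes were higher in males for 15 of 117 and in females for 8 (20 and 12 adjusted over the list alone, and 9 and 4 with the library split). UDP-glucuronosyltransferase 2B31 (1.36) and Probable cytochrome P450 49a1 (1.16) were higher in males, and a Glutathione S-transferase (-2.71) and Probable cytochrome P450 304a1 (-1.71) in females. The P450 304a1 call ended with the library split and without any one library but male 2. Gut and digestive enzymes were higher in males for 4 of 40 and in females for 6 (10 each adjusted over the list alone). Chymotrypsinogen 2 (1.48) and Alpha-amylase 2 (1.16) were higher in males, and Inactive pancreatic lipase-related protein 1 (-1.73) and a protease inhibitor chain, Inter-alpha-trypsin inhibitor heavy chain H3 (-2.27), in females. The Alpha-amylase 2 call ended without any one of the males, and that of the lipase-related protein without any one library but male 2. Pheromone and fatty acid synthesis had 5 of 43 higher in males and 2 in females (8 and 6 adjusted over the list alone). With median-of-ratios scaling these were 3 and 6, with quantile normalization 4 and 6, and with the library split 2 and 1. Elongation of very long chain fatty acids protein 7 had 49.5 ± 3.2 FPKM in males and 17.8 ± 1.6 in females (1.43). One fatty acyl-CoA reductase CG5065 sequence was higher in males (1.11) and another in females (-0.86), the latter not without male 3 or any one of the females. The sex determination list was higher in males for 3 of 13, also adjusted over the list alone, and for 2 with the library split. It was matched on words, and a name alone does not place a sequence in sex determination. Insulin-like growth factor 2 mRNA-binding protein 3 (0.62) and Protein male-specific lethal-3 (0.47) were higher in males, the latter neither with the library split nor without any one of the 6 libraries. The camera adjusted p was 0.048, and the adjusted p = 0.62 with an estimated correlation. Egg, ovary and testis names were higher in males for 2 of 39 and in females for 2 (5 and 3 adjusted over the list alone). Chorion peroxidase (0.83) and 63 kDa sperm flagellar membrane protein (0.76) were higher in males, and Motile sperm domain-containing protein 2 (-0.43) and Spermatogenesis-associated protein 20 (-0.38) in females. Both female calls ended with the library split, the former without any one library but male 2 and the latter without any one but female 1. With median-of-ratios scaling the list had 2 and 4 calls, and with the library split 2 and 0. Of 5 silk gland and salivary sequences, Probable salivary secreted peptide (0.53) was higher in males, a call that ended with median-of-ratios scaling, with the library split and without any one library but female 1. Adjusted over the list alone, 1 was higher in each sex. Transposon and virus names were higher in males for 22 of 617 and in females for 14 (21 and 12 adjusted over the list alone, and 10 and 6 with the library split). They included an RNA-directed DNA polymerase from transposon BS, listed at 0 in all females and at 3.68 ± 1.45 FPKM in males, and one from mobile element jockey (2.17). Higher in females were a type-1 Retrovirus-related Pol polyprotein (-1.82) and BCL2/adenovirus E1B 19 kDa protein-interacting protein 3 (-1.86), a cell death protein matched by the word virus.

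A pseudocount of 0.1 in place of 1 moved the log2 fold changes of some low sequences by over 1.5 times. Those of Alaserpin (3.73), the tolloid-like protein (-3.54) and Probable cytochrome P450 304a1 (-2.73) moved with the end of their call. Those of Arylphorin subunit alpha (-7.32), Pro-neuropeptide Y (2.41), Protein takeout (2.67), Inactive pancreatic lipase-related protein 1 (-2.96), the Glutathione S-transferase (-4.54), mobile element jockey (3.41) and the type-1 Pol polyprotein (-3.14) moved with a limma adjusted p below 0.05. The tolloid-like call ended in 14 of its 18 alternatives. Without the filter on low values, the calls of Insulin-like growth factor 1 receptor and NADH dehydrogenase 1 alpha subcomplex subunit 13 ended. Those of the latter and ATP synthase subunit beta ended with median-of-ratios scaling, and those of ATP synthase subunit beta, Retinol dehydrogenase 11, Transferrin and Protein male-specific lethal-3 with quantile normalization.

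Sequences found in one sex alone were counted without a test. There were 151 with an FPKM of at least 1 in all males that were listed at 0 in all females, and 100 the other way round. Of the male-limited sequences 141 had a name ending in 1, and of the female-limited ones 91 had a name ending in 2. Usable names were carried by 10 male-limited sequences and by 0 female-limited ones. Among the 10, names of mobile elements were the most frequent kind: jockey, transposon BS (more than 1 sequence), transposon X-element and a PiggyBac element. The others were Histone-lysine N-methyltransferase SETMAR, putative nuclease HARBI1, Venom dipeptidyl peptidase 4, Protein lin-28 homolog and Cuticle protein 19. Other splits of the libraries into 3 and 3 gave at most 228 such sequences, with a median of 92, against 251. The number was 8 at an FPKM of at least 5. It was 504 without male 1, 442 without male 3, 393 without female 1, 536 without female 2 and 408 without female 3, where fewer libraries had to be at 0 or above 1. The balance turned without any one of the males: 238 male-limited against 266 female-limited without male 1, 177 against 198 without male 2, and 182 against 260 without male 3. Leaving out a male eases the condition of 0 for female-limited sequences alone, and leaving out a female that for male-limited ones, which numbered 254 against 139 without female 1, 353 against 183 without female 2, and 269 against 139 without female 3. Singled out after their values were seen, Protein lin-28 homolog, an RNA-binding regulator of developmental timing, had 1.95, 4.23 and 2.06 FPKM in males 1, 2 and 3, and Cuticle protein 19 had 1.25, 1.01 and 1.6.

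The 100 most abundant sequences held 37.2% ± 1.1 of the summed FPKM in males and 38.9% ± 0.45 in females (SD, n = 3). The two-sided exact permutation p was 0.1, the smallest that 3 against 3 allows.

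De novo assemblies place related sequences in clusters. Among 4648 clusters with more than 1 tested sequence, 6 had a member higher in males and another higher in females. Shuffling the calls over clusters of the same size 1000 times gave a mean of 11.02 such clusters, with 95% of shuffles between 5 and 17, and a one-sided permutation p of 0.072 for so few. The number of clusters with opposite calls was 1 with the library split in the model and 0 with a replicate block. In a cluster singled out after its values were seen, Chitin deacetylase 1, a cuticle-modifying enzyme, had a log2 fold change of 0.82 and a Mariner Mos1 transposase -1.29. The transposase call ended with the library split in the model.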

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

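The library split, the name endings, the list versions and clusters without the ending were chosen only after the results were seen; all other settings were fixed before. The count of 2501 changed sequences stayed within 1.5 times under other pseudocounts, filters, scalings, robust shrinkage and array weights (2177 to 2649). The sequences were not all the same. With a mean FPKM of at least 5, 9789 were tested and 2517 called, 1589 of them among the 2501. The other fits of this kind shared 2136 to 2470 with the 2501. Changed sequences numbered 1031 with a log2 fold of at least 1 and 1136 with the assembly set term. They were 1520 and 986 for name ending 1 and 2 alone (fewer sequences tested), and 822 to 1776 with 1 library left out (fewer samples). With the replicate block they became 631, members of the other gene lists 86, cuticle proteins 23, neuropeptide and receptor members 0 and opposite clusters 0. Whether the numbers pair the libraries cannot be told from 3 libraries per sex. Residual correlations of same-numbered males and females were 0.11, 0.12 and -0.05. Males 1 and 2 correlated best with their own number, and male 3 with female 2 (0.086). Members of the neuropeptide and receptor lists called were 3 in the main comparison, 5 with median-of-ratios scaling, 1 for name ending 1 alone, and 0 to 4 with 1 library left out. Their direction changed with the filter: 2 male and 1 female calls became 0 and 2 with a mean FPKM of at least 5. That filter leaves out Pro-neuropeptide Y and the Neuropeptides capa receptor. Without a filter there were 2 male and 0 female calls. The other gene lists had 230 calls in the main comparison, 105 with the fold minimum, 125 with the set term, 80 for name ending 2 alone and 97 to 187 with 1 library left out. Cuticle proteins changed numbered 39 in the main comparison and 23 to 30 with 1 library left out. Most were in name ending 1: fitted alone, ending 1 gave 32 and ending 2 gave 7. The 251 sex-limited sequences became 8 at an FPKM of at least 5, and 375 to 536 with 1 library left out. The difference in the share of the 100 most abundant sequences kept its direction in all 8 alternatives. Clusters with opposite calls, 6 in the main comparison, numbered 1 at an adjusted p under 0.01, 1 with the set term and 45 without the name ending. That last count can pool unrelated proteins and is not another count of the same clusters. For example, TRINITY_DN2475_c0_g1_i1 is Protein lethal(2)essential for life with ending 1 and Proteasome subunit alpha type-6 with ending 2. The cause was not tested where none is given. Of 77 called named sequences, 38 kept their call in every fit other than the fold minimum and none turned direction. Count tests were not run, since the values are FPKM. Unknown depth limits what can be said of sequences near an FPKM of 1.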

Other observations

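The proteasome comparison, the tests of explanations and the library split were chosen only after the results were seen, and the scalings, the fold minimum and the leaving out of libraries were fixed before. The proteasome, the complex that degrades tagged proteins, was lower in male heads. Of the 25 sequences that the authors' pathway annotation places there, 21 were higher in females and 0 in males by limma, with a median log2 fold change of -0.53. 26S proteasome regulatory subunit 4 had 34.3 ± 0.5 FPKM in males and 57.3 ± 1.2 in females (mean ± SD, n = 3; log2 fold change -0.72, limma adjusted p = 0.0013). 26S proteasome non-ATPase regulatory subunit 1 had 113 ± 3 and 197 ± 7 (-0.80). The 4 without a call included Proteasomal ubiquitin receptor ADRM1 homolog (-0.32). The count was 21 to 23 under the 3 other scalings, 15 with the library split in the model, and 14 without male 3 (the lowest with 1 library left out). With a log2 fold change of at least 1 required it was 0, and it was 11 for each name ending alone, where fewer sequences were tested. Some subunits, such as Proteasome subunit alpha type-4, have a called sequence in both endings. The counts are therefore of sequences and not of subunits, and the endings are not separate support. Within males 2 and 3 against female 2 the median was -0.57, and within male 1 against females 1 and 3 it was -0.50. The camera adjusted p over 260 pathways was 1.8e-24 with a preset correlation and the adjusted p = 0.94 with an estimated correlation. The group therefore stood out among pathways only in the version of camera with the preset correlation. The Hippo signaling pathway was also singled out after the values were seen. Of its 36 members, 9 were higher in males and 0 in females (camera adjusted p = 0.025, and adjusted p = 0.998 with an estimated correlation). The fly version of that pathway, with 9 of 35 higher in males, had a camera adjusted p of 0.063.

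Among the fat body and hemolymph proteins, sequences of one protein name differed in whether they were called by limma. One Arylphorin subunit alpha sequence was higher in females (log2 fold change -4.71), and another, singled out after its values were seen, had no call (0.17, limma adjusted p = 0.44). One Apolipophorin-3 was higher in females (-3.28), and another, also singled out, had no call (0.36, limma adjusted p = 0.29). The difference between sequences of a name was not tested.

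Cuticle proteins were higher in male heads, with a median log2 fold change of 1.07 over 73 members. The library sets seen from the zeros do not account for it, since the median was 1.04 with the set term, 1.04 within one set and 1.01 within the other. These medians do not speak to the name endings: fitted alone, ending 1 gave 32 cuticle calls and ending 2 gave 7. Thorax tissue carried into the male samples stays open: the 20 most abundant muscle sequences had a median of 0.13 (quartiles -0.18 and 0.36), where the head's own muscle would hide a small share, and of 77 muscle sequences 14 were higher in males, such as Paramyosin, short form (1.99), and 4 in females, such as flightin isoform X1 (-1.36). A different stage or moulting age of the sexes cannot be told apart from sex, because the labels give no stage and the juvenile hormone and ecdysteroid list had a median of 0.0466 with members going both ways. A difference between the sexes remains open and untested.

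Neuropeptide precursors lay above 0 in males for 20 of 22 members, with a median of 0.62, mostly without a call. A smaller share of nervous tissue in the female samples would lower synaptic proteins alike, but their median was 0.18, with quartiles of -0.03 and 0.41. The synaptic list was still shifted the same way, with library medians of 0.13, 0.13 and 0.05 in males 1, 2 and 3 and -0.09, -0.04 and -0.07 in females 1, 2 and 3. Less nervous tissue in the female samples is therefore not excluded, though the synaptic shift was smaller than that of the precursors. A smaller share of the neurosecretory parts also stays open. The library sets do not account for the precursors' shift, since its median was 0.64 with the set term and 0.83 and 0.45 within the sets. Whether sex or the low values of females 1 and 2 underlie it stays open.

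The excess of sequences higher in males differed between the name endings by 28.1 percentage points. A shift between the library sets is not the whole cause, since the gap was still 23.7 points with the set term. Another candidate explanation is that sequences of each ending were assembled from a different set of libraries, which would favour sequences present in that set. Among sequences with a mean FPKM of at least 10 the gap was 9.0 points, and 12.0 with the set term. The former is under 0.5 of the 28.1 points without the set term. The latter is just above 0.5 of the 23.7 points with it, so by the rule set this stays open. Of male-limited sequences 93.4% had ending 1 and of female-limited ones 91.0% had ending 2 (53.6% of all sequences have ending 1), which restates the zeros that define the library sets and decides nothing about the assembly.

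The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share below 0.05. In 1 of the 10, the real one, as many sequences differed: 2501, against at most 0 in the others, with 8214 at an unadjusted p below 0.05 against at most 2348. That highest other value came from the split that follows the library sets. The neuropeptide and receptor lists had 3 calls and the other lists 230, against at most 0 each. The preset-correlation camera p of the cuticle proteins was 4.1e-24, and the smallest in another split was 6.5e-06. Each of the other splits holds 2 libraries of one sex against 1 in each of its groups.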
